A study of Lates calcarifer with 8 samples.

How the data were processed

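The samples were brains of the Asian seabass (Lates calcarifer, also called barramundi), a food fish in which most animals mature first as males and later turn into females. Per the labels, the fish were adults of 5 years, 4 females with ovaries at the stage labelled F3 and 4 males with testes at the stage labelled M3, and the whole brain was taken with the pituitary attached. Per the labels' protocols, total RNA was purified with silica columns, only extracts with an RNA integrity number above 8 were used, and 100 ng went into a 1-colour Cy3 labelling reaction that amplifies the RNA. Labelled material went on to hybridization only with a yield above 0.825 µg and a specific activity above 6 pmol of dye per µg. Each animal was hybridized to its own array of a custom oligonucleotide design, so the unit of replication is the fish, with 4 fish per sex.

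The spot intensity values deposited for each array had been made with Agilent Feature Extraction 10.7.1.1, per the file headers. This software had subtracted the background and removed a spatial trend within each array, and the level of signal still differed between arrays. Each scanner table held 61580 spots for 60080 probes besides 1319 control spots, and 300 probes lay on 6 spots each. All 8 arrays lay on 1 slide and came from 1 scan, so slide and scan date could not differ between the sexes. The arrays sat in a grid of 2 rows and 4 columns on the slide. Slide row 1 held females 1 and 2 and males 1 and 2, row 2 held the other animals, and each column held 1 female and 1 male. The 4 animals with the lowest numbers in their labels were also the 4 animals of row 1, so row and order of numbering coincide.

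The authors also deposited a table of log2 values for the same arrays, and the submitters' processing notes name only Partek, with no version; its steps are not given in the sources used here. Its columns correlated with the log2 processed signal of their own array at r from 0.99927 to 0.99997 across probes, and with any other array at 0.97012 or less. Sorted values differed between columns by at most 0.0018 and every column had a median of 4.48, so the scale was log2 with the arrays forced to 1 distribution and no centring of probes. This table served as an alternative.

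Control spots were left out, spots that the scanner software had marked as outliers were set to missing (25 to 163 per array), and spots of 1 probe were averaged. The main values were log2 of the processed signal minus the same array's 75th percentile of it. A probe was tested if it was well above background on at least 4 of the 8 arrays, which left 32851 probes and removed 27229. The comparison used lmFit and eBayes of limma 3.58.1 in R 4.3.3 without covariates, a two-sided moderated test with Benjamini-Hochberg adjustment over all tested probes at a threshold of 0.05, and differences are female minus male throughout. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. Where a called probe was well above background on all arrays of 1 sex and on none of the other, its fold is given as a lower bound. That bound sets the bright sex's mean against the mean, over the dim sex's arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array.

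The test was tried on simulated data, using the 32684 tested probes without missing values. Each probe had its mean level and its spread as estimated by limma from the real arrays, with independent normal noise of equal spread on every array. In each of 20 runs 200 probes were changed by known amounts between 4 female and 4 male arrays. It recovered 15.6% of the 2-fold changes, 79.8% of the 4-fold, 96.2% of the 8-fold and 98.5% of the 16-fold changes, and 5.47% of the calls were false. With no probe changed, 1 of 20 runs gave a call. The simulated data held no row effect, no deviations of single arrays and no unequal noise between arrays. On the real arrays the estimated array weights ran from 0.44 for female 2 to 2.01 for female 3. The shares recovered and false therefore hold for the simulated setting and may differ on the real arrays. The number of arrays limits the precision. Within an array, the spots of a repeated probe varied with a median coefficient of variation between 8.27% for male 3 and 25.4% for female 2.

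The alternatives set before the data were examined were a different background correction, quantile normalization, median scaling, no filter on dim probes, a filter that needs all 8 arrays, an intensity trend with robust estimation, array weights, slide row or slide column as a block, the authors' table, and each array left out in turn. The background correction was planned as normexp on mean spot signals, which the scanner tables used here lack, so it was run on median spot signals with local background and an offset of 50. Cyclic loess, a correction of each spot by the median deviation of its 24 nearest spots, and a fit without the 2 arrays of widest spot spread were added after seeing the data.

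The scanner tables give each probe an identifier and a target identifier of the array's own design but no gene name. None of the 60080 target identifiers matched the 32906 genes of the reference gene table used here (0 matches). Gene lists, a pituitary hormone score, that score as a covariate and 1 value per gene had been planned and were not run for this reason. The naming rule, set before the data were examined, then allowed at most 2 probes higher in females and 2 higher in males, those with the smallest p, given by identifier.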

Results

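Messenger RNA levels were measured in whole brains, pituitary included, of 4 female and 4 male adult Asian seabass, each on an array of its own. The probes of this custom array report transcripts of the species and are known here only by identifier. The 75th percentile of the processed signal was 126, 93.1, 128 and 129 intensity units in females 1 to 4 and 123, 109.8, 105 and 108 in males 1 to 4. Between 49.2% of spots (female 2) and 59.5% (female 1) were well above background, and no spot was saturated (0 on every array). No array was a near copy of another, since correlations between arrays across tested probes lay between 0.922 and 0.976.

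The design asks which transcripts differ between the brains of females and males. Of 32851 probes tested, 25 differed between the sexes, 20 with more signal in females and 5 with more in males. Fitted log2 differences ran from 1.52 to 5.40 for the female-higher and from -1.71 to -3.07 for the male-higher probes. For 5 female-higher and 2 male-higher probes the dimmer sex was not well above background on any array, so their folds are lower bounds. With these probes at their bounds, the median was 5.34-fold for the female-higher and 3.34-fold for the male-higher probes. By such a bound or by measurement on all 8 arrays, 5 of the 20 and 0 of the 5 exceeded 8-fold. Another 4 of the 25 were well above background on only some arrays of the dimmer sex; their folds, 2 of them over 8-fold in females, are fitted values that rest partly on signal near background and enter the medians as such. In all 25 probes the 4 arrays of one sex lay entirely above the 4 of the other. The 25 were chosen on these same values, so their separation adds no support to the calls. Among all tested probes 3.76% were separated in this way, where chance gives 2.86%.

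The smallest p belonged to probe CUST_10564_PI428621111 (target SBRGG_30397), which was well above background in 4 of 4 females and 0 of 4 males. Its log2 signal relative to the array's 75th percentile was -0.63 ± 0.16 in females and -4.97 ± 0.19 in males (SD, n = 4 each). The fitted difference was 4.34 ± 0.17 (SE; limma, adjusted p = 4.26e-05). Because the males were not well above background, its signal is given as at least 5.51-fold higher in females on the processed signal. Under the normexp setting its difference was only 1.03 on the log2 scale, so the size of the difference depends on the processing. That setting changes the signal measure and the background and adds an offset. These parts were not separated, so the drop cannot be put down to the background correction alone. Probe CUST_36452_PI428621111 (target SBRGG_40442) was measured on all 8 arrays, at 2.94 ± 0.10 in females and 0.05 ± 0.12 in males (SD, n = 4 each). Its difference was 2.89 ± 0.15 (SE; limma, adjusted p = 0.000278), a 7.39-fold higher signal in females.

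Among probes higher in males, CUST_43502_PI428621111 (target SBRGG_21703) was well above background in 4 of 4 males and 0 of 4 females. Its log2 signal was -0.51 ± 0.44 in males and -3.59 ± 0.55 in females (SD, n = 4 each), at least 5.54-fold higher in males on the processed signal (fitted difference -3.07 ± 0.32, SE; limma, adjusted p = 0.0158). Under normexp this difference was -1.14. Probe CUST_46661_PI428621111 (target SBRGG_44619) was at -1.27 ± 0.28 in males and -2.98 ± 0.19 in females (SD, n = 4 each) and well above background in 4 males and 1 female. Its difference was -1.71 ± 0.20 (SE; limma, adjusted p = 0.0223). The call for CUST_43502_PI428621111 ended without male 1, 2 or 3 (adjusted p = 0.0619, 0.0850 and 0.0665, limma), with slide column as a block (adjusted p = 0.283) and without the 2 arrays of widest spot spread, female 2 and male 1 (adjusted p = 0.139). That for CUST_46661_PI428621111 ended in 6 of the 8 fits that left out 1 array, all but those without female 2 or male 4, with adjusted p from 0.0701 to 0.104 (limma). It also ended under normexp background correction, where its difference was -0.60 (adjusted p = 0.300, limma). Without a filter, with slide column as a block, after the local correction and without the 2 arrays of widest spot spread it ended as well, with adjusted p = 0.0729, 0.485, 0.0543 and 0.139 (limma).

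**Figure D1:**
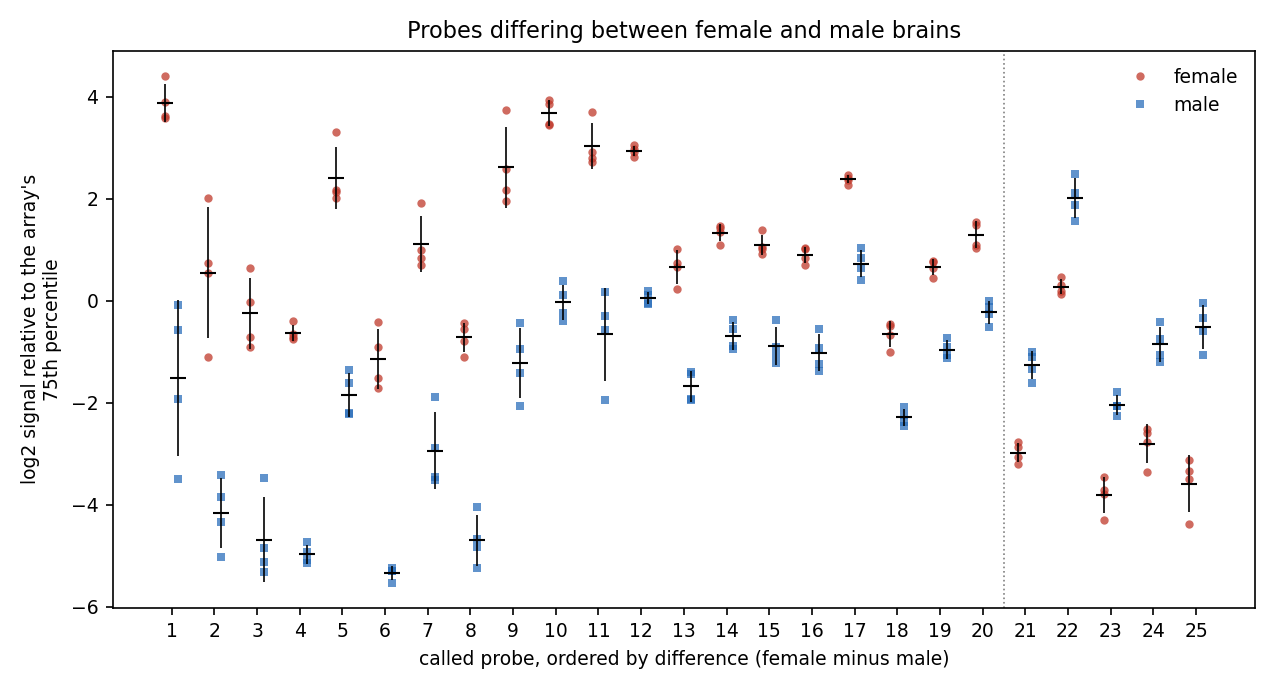
Log2 signal of the 25 probes that differed between the sexes, relative to each array's 75th percentile (vertical axis), with the probes ordered from the highest female minus male difference to the lowest along the horizontal axis. Points are single animals (circles female, squares male; 4 each), black bars are the mean ± SD, and the dotted line parts the 20 female-higher from the 5 male-higher probes; the sexes do not overlap in any of the 25.

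The called probes covered a wide range of signal. Of the 20 female-higher probes, 13 were well above background on all 8 arrays and differed by 2.87- to 19.1-fold. Another 5 were well above background in 4 of 4 females and 0 of 4 males, with lower bounds from 3.86- to 12.5-fold, and 2 were so on some male arrays. Of the 5 male-higher probes, 1 was measured on all 8 arrays, 2 were well above background in every male and no female (at least 1.92- and 5.54-fold), and 2 were so on some female arrays.

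The comparison covers few animals, and the counts moved with single arrays. Without female 1, female 3, male 1, male 2 or male 3 in turn, limma called 13, 10, 9, 11 and 10 female-higher probes, and 2, 3, 0, 0 and 0 male-higher ones, and without male 4 it called 2 male-higher probes. Slide row 1 alone, with 2 animals of each sex, gave 0 calls in limma (6.78% of probes at an unadjusted p under 0.05) and row 2 alone gave 11 (11.4%). Of these 11, 5 were among the 25. Columns 2 and 4 held the females in row 1 and the males in row 2, so calls within 1 row mix sex with column position. Tested directly over all probes, the sex difference differed between rows for 3773 probes (11.5%) at an unadjusted p under 0.05. At an adjusted p under 0.05 it did so for 2. In this layout that test is the same contrast as slide columns 2 and 4 against columns 1 and 3. A sex difference that changes between rows and a shift of those columns therefore cannot be told apart. With slide row as a block, 17 probes were called higher in females and 4 in males, 18 of them among the 25. With slide column as a block, where each column pairs 1 female with 1 male, 9 were called higher in females and 0 in males (limma; 4.39% of probes at an unadjusted p under 0.05), and 9 of the 25 calls were kept.

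Most of the measured brain transcriptome showed no difference between the sexes that 4 animals against 4 could resolve. At an unadjusted p under 0.05, limma found 1639 probes (4.99%, with 1643 as the nominal count), 674 higher in females and 965 higher in males. With slide row as a block it found 2052 (6.25%). Of the 18 splits of the animals balanced over rows, 2 gave at least 1639, the real one included. The highest other gave 2307, and this split set slide columns 2 and 4 against columns 1 and 3. The next highest gave 1568. The median of the others was 799, so the nominal count is not the level that such groupings typically gave. The 95% confidence interval of the sex difference had a median half-width of 0.58 on the log2 scale. It excluded a 4-fold difference for 94.8% of tested probes and a 2-fold difference for 66.6%. Differences under 2-fold were therefore not resolved for many probes.

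No test placed sex among the main axes of variation of these brains. The difference between the sexes accounted for 15.6% of the total variance of the tested probes (exact permutation over 35 splits of the 8 animals, p = 0.314). Among the splits balanced over rows, only that of slide columns 2 and 4 against columns 1 and 3 had a larger share, 16.2%. The first 3 principal components held 27.3%, 18.7% and 14% of the variance. Along none of them did the difference between the sexes pass the test (two-sided exact permutation tests, p = 0.514, 0.171 and 0.143, or 0.514, 0.257 and 0.257 after adjustment over the 3). These tests did not hold slide row fixed. Along the second component the females lay below the males within each row, and this was not tested within rows. The scores were 27.2 and -49.3 against 76.7 and 36.5 in row 1, and -30.2 and -31.6 against -12.8 and -16.5 in row 2. Along the first component every animal of slide row 1 lay below every animal of row 2 (exact permutation p = 0.0286, the smallest that 35 splits allow, adjusted p = 0.0857). Pairs of animals of the same sex correlated across probes at a median r of 0.948 (12 pairs) and pairs of opposite sex at 0.949 (16 pairs). Pairs within row 2 stood at 0.966 and pairs within row 1 at 0.945 (6 pairs each). Pairs from different rows stood at 0.946 (16 pairs), so arrays of row 1 were no more alike than arrays of different rows.

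**Figure D2:**
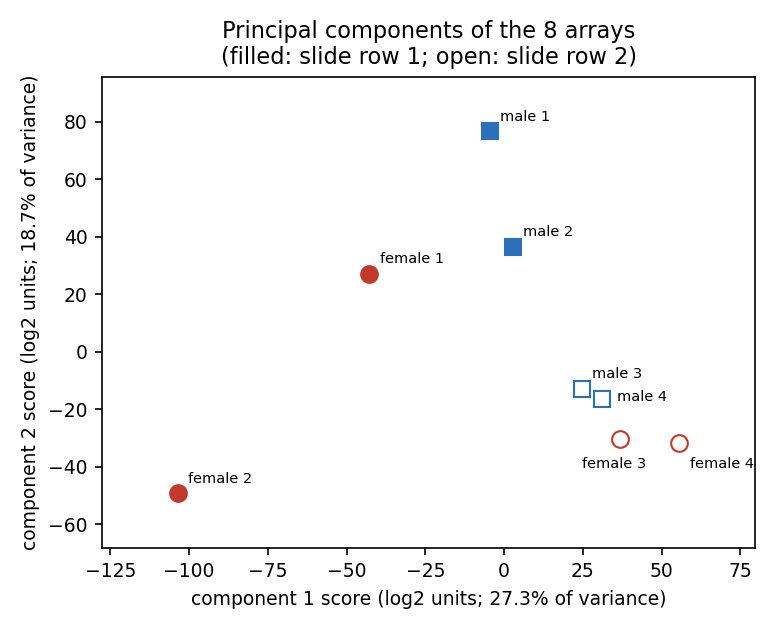
Scores of the 8 arrays on the first and second principal components of the tested log2 values (axes in log2 units, 27.3% and 18.7% of the variance). Circles are females, squares males, filled symbols slide row 1 and open symbols row 2; row 1 arrays lie left of the row 2 arrays, and the sexes do not separate along the horizontal axis.

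Detection in only one sex was also compared. Counting probes well above background on every array of one sex and on none of the other, 15 were found in females only and 19 in males only, of which 5 and 2 were among the 25 called probes. Such a total of 34 or more arose in 15 of the 35 splits of the 8 animals into 4 and 4 (exact permutation p = 0.429), so the count did not exceed what other groupings of these animals gave.

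Repeated spots give the spot-to-spot part of the error, which leaves out the labelling and hybridization of each array. For the 275 probes on 6 spots that were well above background on all arrays, single spots of a probe varied within an array with a median SD of 0.19 on the log2 scale. Averaged over 6 spots this comes to 0.08. The SD between animals of one sex, which also holds the labelling and hybridization of each array, was 0.25 for these probes and 0.32 for 225 single-spot probes of matched signal level. None of the called probes was among those on 6 spots (0 of 25), so each call rests on 1 spot per array.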

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

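Slide row as a block was planned; the other tests of explanations in this part, the local correction and cyclic loess included, were chosen after the data were seen. For the neighbours of called probes, the probes called in row 2 alone and both corrections, the bounds were set before the test's own result was seen; for the splits, the neighbours of single-array deviations and the negative control spots they were set after it.

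Female 2 had a 75th percentile of signal of 93.05, apart from the other 3 females at 126 to 128.6. It was the only sample far from its group among 24 sets of 4 samples examined, and chance gives about 1 in 20 such sets.

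The 25 probes called between the sexes were set against all 35 splits of the 8 arrays. A result as large came from 2 (exact permutation p = 0.0571), the real one and the split by slide row with 31 probes. The next highest split gave 1 call. The row split follows a structure of these samples, but the count as tested does not exclude chance. With row as a block, 1 of the 18 splits balanced over rows, the real one, reached the real 21 calls (highest other 1). For probes whose groups lay over 4-fold apart, 1 of 6 measures compared over splits, 1 of 18 reached the real 16 (highest other 2). These 18 splits are too few for a share under 0.05. Over all 35 splits only sex reached 16 (highest other 7, exact permutation p = 0.0286, not adjusted over the 6 measures). For the 21 calls with row as a block, 34 splits gave an exact permutation p of 0.0294, but these include splits unbalanced over rows. Defects shared by neighbouring spots are argued against. The 8 nearest spots differed by only 0.01743 in the probe's own direction (95% of random sets -0.05795 to 0.09552). The called probes themselves differed by a mean of 2.977. An additive shift of a whole row or column cancels from the sex difference by design. An effect that alternates over rows and columns together does not cancel. Females sat in columns 2 and 4 of row 1 and in columns 1 and 3 of row 2. The part of a sex difference that changes between rows cancels from its mean over the rows. In this layout that part is the same contrast as columns 2 and 4 against columns 1 and 3. When tested directly, 3773 probes had such a contrast at an unadjusted p under 0.05. It cannot be assigned to sex or to columns. Sex of the animals stays open as a hypothesis. Of the 11 probes called in row 2 alone, 9 went the same way in row 1, against 45.4% of all tested probes. Their mean difference in row 1, signed by that in row 2, was 2.343 over the 11 (central 95% of random sets -0.414 to 0.335). This lay under the bound of 2.44 set to exclude an origin in row 2, which stays open for these 11. For the 1639 probes at an unadjusted p under 0.05, 9 of 35 splits gave as many (highest other 4566, by slide row). Of the 18 balanced splits 2 did, the real one and that of columns 2 and 4 against columns 1 and 3, with 2307. The next highest gave 1568 and the median of the others was 799. These 18 splits are too few for a share under 0.05, so chance is not excluded.

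The split by slide row called 31 probes, 6 higher in row 1 and 25 in row 2, none shared with the sex calls (0), and 4566 probes (13.9%) had an unadjusted p under 0.05 against 1639 for sex. This points to a structure of the samples other than sex. Gradients or defects within arrays, or scaling that depends on signal, are argued against as the whole cause of that excess, since 4509 probes passed this threshold after the local correction (3397 of them shared) and 4598 after cyclic loess (4334 shared). The calls went from 31 to 26 and 24, of which 20 and 24 were shared, so a part played by such gradients in single calls stays open. Array quality differed between rows, with 59 to 136 spots marked as non-uniform on row 1 arrays and 4 to 31 on row 2 arrays. Whether this gave the row calls was not tested. Row coincides with the order of the animals' numbers. A hybridization effect that differs between rows and a difference in the animals or their handling therefore both stay open, and no biological explanation was tested.

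On single arrays, 2453 probes lay over 4-fold above all other arrays, 1886 of them on row 1 arrays, and 2105 were not well above background elsewhere. Local defects may account for them: on 8 of 8 arrays the nearest spots of such probes also stood apart more than 3 times as often as all spots (8.40 to 32.8 times). Negative control spots, which match no transcript, were over 4-fold above the same spot on all other arrays in 1.43% of cases, against 1.48% of probes not detected elsewhere. When control spots that the scanner software had marked as population outliers were left out, none remained (0 of 197 spots per array), but this mark fell on 0 spots of single-spot probes. No biological explanation was tested, since the design gives none for single animals.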

How the results depend on the processing

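Cyclic loess, the local correction and the fit without female 2 and male 1 were chosen after seeing the data. No result reversed, but for the 25 called probes the complete separation of the sexes fixes the direction when arrays are left out or a block is added. Against 20 probes higher in females, 10 were called without a filter, 9 with slide column as a block and 7 without the 2 arrays of widest spot spread. Of the 25 calls these fits kept 11, 9 and 6. Of probes higher in males, against 5 there were 2 under normexp background correction, 1 without a filter, 2 with a filter on all 8 arrays, 8 with array weights, 0 with slide column as a block (4.39% of probes at an unadjusted p under 0.05) and 1 without those 2 arrays. Fewer arrays and fewer residual degrees of freedom, or more probes to adjust over, account by construction for part of the drop in the column, spread and no-filter fits. The filter on all 8 arrays left only 1 of the 5 male-higher probes in the test, so that drop follows from the filter. All 14 main calls that it still tested were kept. Elsewhere the cause was not tested. Leaving out 1 array gave 9 to 25 female-higher and 0 to 4 male-higher probes, and 7 probes, all female-higher, were called in each of these fits. The probes at an unadjusted p under 0.05 rose from 1639 to 2594 with array weights and stayed within 1.5 times under the other alternatives. The share of variance along the sexes lay between 13.8% and 15.7% with all arrays. With the authors' values 24 of the 25 calls were kept, with normexp 16. For the 4 named probes, 65 of 81 values kept their side of the threshold and 16, all of the 2 male-higher probes, passed it no longer. Under normexp, CUST_10564_PI428621111 differed by 1.03 and CUST_43502_PI428621111 by -1.14; that setting changes the signal measure and the background and adds an offset of 50, which narrows differences of dim probes by construction, and these parts were not separated. The planned block for slide or scan did not apply, and gene lists, the pituitary score, that score as a covariate and 1 value per gene were not run for want of gene names.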

Other observations

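The test of nearby target numbers and the count over splits were chosen after the result was seen.

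Among 59790 probes, 90 had 3 to 5 arrays over 4-fold apart from the rest. In 15 of these the 4 females stood above the 4 males, in 1 the males stood above, in 7 the rows of the slide parted, and 67 followed 43 other groupings with at most 5 probes each. Over the 35 splits into 4 and 4 alone, sex had the most such probes, 16 against at most 7 in any other split.

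Whether the called probes vary together within a sex was tested. Their deviations from the sex means, each turned by the sign of the probe's sex difference, had a mean pairwise correlation of 0.04035 across the 8 arrays, against a 95th percentile of 0.05388 in 10000 random sets of 25 probes (one-sided permutation p = 0.0882). A factor shared by the animals, such as a differing share of some tissue in the dissected brain, would give a value above that percentile. The observed value lies below it by less than the SD of the random sets (0.0264), so such a factor stays open.

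Some called probes may report the same transcript. Of the 25, 2 pairs had target numbers at most 2 apart, where random sets held a mean of 0.0217 such pairs (one-sided permutation p = 0.0001, the smallest that 10000 random sets can give). Across the 19353 pairs of tested probes with consecutive target numbers, the median correlation of deviations from the sex means was 0.0688, against 0.00169 for random pairs. The 25 calls may therefore stand for fewer transcripts, which the identifiers alone do not settle.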
